A study of Mus musculus with 6 samples.

How the data were processed

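Formalin-fixed cryosections of mouse cholangiocarcinoma were hybridised with the GeoMx mouse whole transcriptome probes and stained for Desmin, CD45 and nuclei, and the tags of Desmin-positive, CD45-negative areas were collected, amplified and sequenced, per the labels' protocols and the series' design text. How the places of the regions were chosen is not given in the sources used here. The deposited table holds a signal value for each of 13264 targets and a negative probe in 6 regions, 3 per genotype, and per the file headers its second line repeats the genotype. The counting of tags, the choice of targets and the scaling that the authors applied before they deposited the signal values are not given in the sources used here. In each column 99.98% of the values were whole multiples of a single step within 0.01 step, and the smallest value was 2, 2 and 4 steps in the control-labelled and 1 step in the floxed-labelled regions, so the values look like tag numbers times a factor per region whose basis is unknown. Column totals, upper quartiles and negative probes all differed between regions. Whole tag numbers were not established for all columns, and no count model was used. All 6 columns were used, and 0 columns of values were left out.

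Groups were taken from the genotype in the labels. The comparison was floxed-labelled minus control-labelled regions, 3 against 3, with the region as the unit, since no label names the animal. An exact permutation test of 3 against 3 cannot go below a two-sided p of 0.1, so single genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(value + 1) as deposited. Targets were kept where their mean lay above that of the negative probe, which removed no target. P-values were adjusted by Benjamini-Hochberg, with calls at an adjusted p under 0.05. This design, the gene lists and the alternatives were fixed before the data were examined. Because the median target then shifted by -1.22 on the log2 scale, a scaling chosen in advance, in which each region is scaled to a common upper quartile (the 75th percentile, Q3), is also given as a comparison of its own, in the same fit and with every alternative repeated on it. That choice was made after the shift was seen, and gene levels in the text are on this scale unless stated otherwise. Errors are SD over the regions of a group, or SE of limma's log2 change where so marked.

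In all 36 gene lists were fixed, for fibroblast programmes, signalling, metabolism and the other cell types that the mask could hold, and 34 had at least 5 tested members. They were tested against all other targets with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and fry beside it. Member counts are given over all targets and adjusted over the list alone, both from the Q3-scaled fit unless stated otherwise. Genes were named by a rule fixed in advance. It takes Cd274, Col1a1, Des and Ptprc, up to 8 called genes with the largest change and no overlap between groups in each direction, up to 4 members with the smallest p of each list called by camera and of 7 fixed lists, and the 2 most abundant members of each list of another cell type. The rule did not say on which scale. The part on largest changes was applied on both scales, and the smallest p was taken from the Q3-scaled fit, choices made after the files were seen. The rule named 110 genes, of which not every one is printed. Genes outside it that the text names were chosen after their values were seen: Stat2, Irf1, Irf7, Eln, Scd1, and the genes that open the other observations. The counts of interferon and MHC members under left-out regions and other settings, and the overlap of higher genes with those lists, were added after the data were seen.

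Target names are symbols. Of them 13203 are symbols and 13 are synonyms in the reference gene table of assembly GRCm38.p6, and 48 matched neither and were used as given. No genome build is given in the sources used here, so no coordinates are printed.

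The fits were tested on simulated data with the real means and limma's moderated spreads of 13264 targets, drawn independently, and 200 changed genes. As deposited, 11% of changes of 1 and 75% of changes of 2 on the log2 scale were called, with 4 unchanged genes called. After Q3 scaling these were 24%, 83% and 7. The simulation held no shared shift between groups, no correlation between genes and the same spread in both groups. These rates therefore need not hold for the real regions. Alternatives were other scalings (Q3, total, quantile, negative probe), filters, pseudocounts of 0.5 and 5, variance models, region weights, a threshold of 0.1, subtraction of the negative probe, and leaving out each region in turn. Bootstrap intervals at 95% used 10000 resamples of genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.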

Results

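In all, 6 regions of mouse cholangiocarcinoma were profiled with the GeoMx whole transcriptome assay, in which gene-specific probes carry sequencing tags that are released from a chosen area of a tissue section and counted. In each region the collected area was Desmin-positive and CD45-negative, a mask for cancer-associated fibroblasts and activated hepatic stellate cells. The tumours came from the SB cell line. Per the labels, 3 regions came from mice with intact Cd274 alleles and a Col1a1-driven Cre (control-labelled), and 3 came from mice with both Cd274 alleles floxed and the same Cre (floxed-labelled). Cd274 encodes PD-L1, a ligand that restrains T cells. The comparison asks how the transcriptome of this mask differs where Cd274 is floxed in Col1a1-Cre mice. Per the file headers all 6 regions lay on the same slide, with areas 11 to 13 floxed-labelled and 14 to 16 control-labelled. The genotype therefore cannot be told apart from such a block of areas. No label ties a region to an animal, so regions of a group may share an animal. The p-values below rest on the spread between regions, on the deposited scale on its trend over all genes rather than each gene's own. If regions share an animal, they may be too small.

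The table held 13264 targets and a negative probe in 6 columns. The summed signal was 720786, 724323 and 1024180 in control-labelled regions 1, 2 and 3, and 378554, 223253 and 393615 in floxed-labelled regions 1, 2 and 3. The group means were 823096 ± 174151 and 331807 ± 94312 (SD, n = 3 each), a 2.48-fold difference. The negative probe, which binds no mouse transcript, read 7.80 ± 1.41 in the control-labelled and 3.59 ± 0.40 in the floxed-labelled regions (SD, n = 3 each). The median target lay 4.14 ± 0.23 and 3.89 ± 0.42 times above the negative probe in the respective groups. Each column's values were whole multiples of a step of its own. If a step is 1 tag, the median target rested on 26, 36 and 40 tags in the control-labelled and on 11, 11 and 19 tags in the floxed-labelled regions. Counting error alone would then be 15.8% to 19.6% and 22.9% to 30.2% of the median value. Across genes, the log2 values of the control-labelled regions correlated with Pearson's r of 0.921 to 0.939, and those of the floxed-labelled regions with r of 0.686 to 0.806, where genes are not independent replicates. Floxed-labelled regions 1 and 3 correlated with the control-labelled regions at 0.825 to 0.859, above every correlation within their own group, and floxed-labelled region 2 at 0.716 to 0.736. Floxed-labelled region 2 had the lowest signal and took part in the lowest of these correlations.

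**Figure D1:**
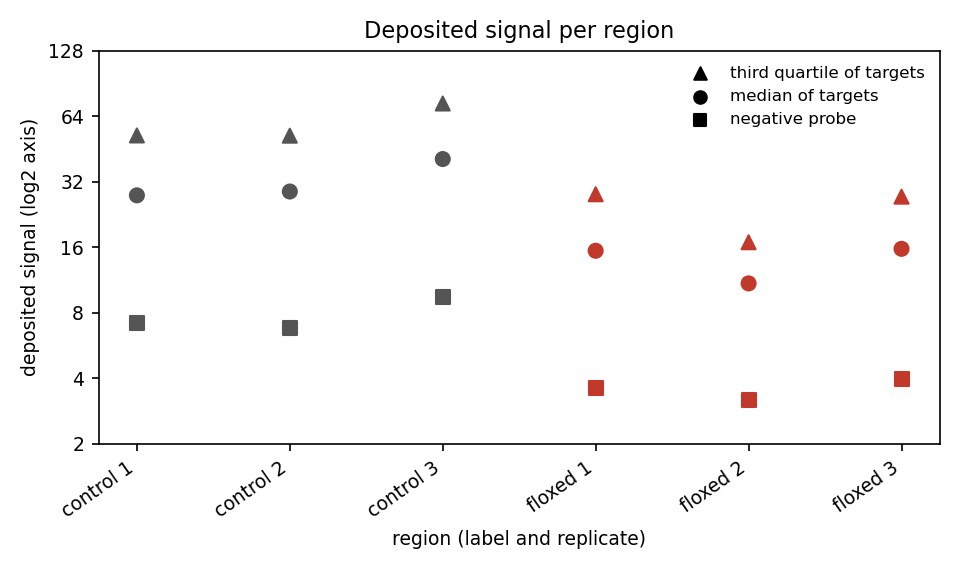
Deposited signal of each region on a log2 axis, with the upper quartile and the median of all targets and the negative probe as separate symbols, control-labelled regions in grey and floxed-labelled regions in red. Every floxed-labelled region lies below every control-labelled region for all 3 quantities, and the mean negative probe falls from 7.80 to 3.59.

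Cd274, the floxed gene, did not separate the groups. As deposited it read 14.9, 20.04 and 26.4 in the control-labelled regions and 8.41, 7.94 and 21.5 in the floxed-labelled regions, a log2 change of -0.76 ± 0.40 (SE) with an adjusted p of 0.0712 (limma, Benjamini-Hochberg). After each region was scaled to a common upper quartile (Q3), the direction turned, at 12.7 ± 1.91 against 19.2 ± 9.17 (SD, n = 3 each) and a log2 change of 0.47 ± 0.36 with an adjusted p of 0.610. Total, quantile and negative-probe scaling turned it too. Cd274 lay only 2.61 ± 0.45 and 3.41 ± 1.73 times above the negative probe (SD, n = 3 each). The part of the transcript its probe covers, against the deleted part, is not given in the sources used here, and cells without Cre in the mask would keep the gene. Its level therefore does not check the labels, and every direction below is drawn from the labels alone. Col1a1, whose promoter drives the Cre, read 2982 ± 666 and 1729 ± 467 after Q3 scaling, a log2 change of -0.80 ± 0.37 with an adjusted p of 0.399. Des and Ptprc encode the proteins used to choose the cells, and so are no findings. Des read 31.4 ± 8.07 and 36.5 ± 12.6, and Ptprc 26.1 ± 4.63 and 47.8 ± 15.9, with adjusted p of 0.853 and 0.274.

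On the deposited scale nearly the whole transcriptome was lower in the floxed-labelled regions. Of 13264 targets, 9905 were lower and 21 were higher at an adjusted p under 0.05 (limma, Benjamini-Hochberg). The median target changed by -1.22 on the log2 scale and the negative probe by -1.11, so that the calls mostly carry a shift shared with background signal. The 8 largest increases stood out against this shift. They were Igha, Igkc and Jchain, which encode parts of secreted antibodies, Mup13, a major urinary protein, Saa1 and Saa2, acute-phase serum amyloids, Fabp1, the liver fatty acid-binding protein, and Cxcl9, an interferon-induced chemokine that attracts T cells. Igha rose by 4.68 ± 0.48 (SE) and Cxcl9 by 1.46 ± 0.39, with adjusted p of 1.16e-18 and 0.00111. In this fit limma gave the mean-variance trend infinite weight, so each gene's spread was the trend's value at its mean level. These SE and adjusted p, and the calls on this scale, therefore do not measure a gene's own spread between regions. Igha read 7.46, 10.4 and 31.5 in the control-labelled and 1739, 182 and 166 in the floxed-labelled regions. The 8 largest decreases were those of Grb10, Ibsp, Ppp1r1b, Gsta3, Cyp1b1, Egflam, Fabp4 and Gpx3, from -3.62 ± 0.46 for Grb10 to -3.11 ± 0.46 for Gpx3. Of these 8 genes, Ppp1r1b, Gsta3, Egflam, Fabp4 and Gpx3 kept no call after Q3 scaling, with log2 changes of -2.13 ± 0.63, -1.89 ± 0.45, -1.87 ± 0.43, -1.86 ± 0.50 and -1.83 ± 0.37 (SE) and adjusted p of 0.180, 0.093, 0.084, 0.147 and 0.0505, so a lower level beyond the shared shift is not excluded for them. The groups' ranges did not overlap for 75.6% of targets, where chance gives 10%. Without control-labelled region 3 the lower calls dropped to 5716, and the higher calls ran from 9 without control-labelled region 1 to 41 without floxed-labelled region 2 (10 without control-labelled region 2, 12 without floxed-labelled region 3).

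With each region scaled to a common Q3, a scaling chosen in advance but made a comparison of its own after the shift was seen, 78 genes were higher and 15 lower in the floxed-labelled regions (limma, Benjamini-Hochberg, adjusted p under 0.05). This split of 83.9% higher calls stands against 0.212% as deposited, and the median target moved by 0.02. All log2 changes are on the log2(value + 1) scale, which understates those of low genes. Antibody transcripts were among the largest increases. Igha read 5.29, 7.40 and 15.9 in the control-labelled and 2297, 398 and 225 in the floxed-labelled regions, a log2 change of 5.94 ± 0.66 (SE, adjusted p 0.00301). In the control-labelled regions it lay 1.04, 1.52 and 3.35 times above the negative probe, near background, so the size of this change is uncertain. Igkc changed by 4.69 ± 0.65 (adjusted p 0.00717) and Jchain by 2.97 ± 0.58 (adjusted p 0.0435). In the control-labelled regions Igkc and Jchain lay on average 3.06 and 2.40 times above the negative probe, so the sizes of their changes are uncertain too. Igha, Igkc and Jchain were all highest in floxed-labelled region 1, without which the changes were 4.97, 3.74 and 2.08. With a region left out in turn, the calls held in 6 of 6 fits for Igha, 5 of 6 for Igkc and 2 of 6 for Jchain. Liver-secreted and liver-metabolic genes followed. Mup13 rose from 132 ± 90.1 to 2309 ± 1490 (SD, n = 3 each), Saa2 from 19.1 ± 6.73 to 318 ± 245, Saa1 from 70.4 ± 19.2 to 558 ± 393 and Fabp1 from 26.8 ± 4.42 to 254 ± 151. Their log2 changes were 4.17 ± 0.51, 3.78 ± 0.45, 2.78 ± 0.41 and 3.04 ± 0.36 (SE). Floxed-labelled region 3 was the highest for Mup13 (1642, 1269 and 4016), Saa2 (135, 222 and 597) and Saa1 (268, 401 and 1005), and without it their changes were 3.68, 3.19 and 2.24. Fabp1 was highest in floxed-labelled region 1, without which it changed by 2.59. Saa1 lost its call without control-labelled region 1 or 2, and the other 3 kept theirs with each region left out. Probes for Mup13, Saa1, Saa2 and antibody genes may also bind near-identical family members, so the single gene is uncertain.

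Among the 15 genes that fell, Grb10, an adaptor that dampens insulin and growth factor receptors, read 133 ± 36.1 in the control-labelled and 29.8 ± 23.9 in the floxed-labelled regions (SD, n = 3 each), a log2 change of -2.35 ± 0.42. Cyp1b1, a cytochrome P450 of hormone and xenobiotic metabolism, read 186 ± 44.7 and 49.0 ± 5.18, a log2 change of -1.88 ± 0.24 with an adjusted p of 0.00461 (limma, Benjamini-Hochberg). Ibsp, a mineral-binding matrix sialoprotein, fell by 2.21 and reached the level of the negative probe, 0.874 times it, in the floxed-labelled regions, so the size of this change is uncertain. Gsta4 and Tst, enzymes of detoxification, fell by 1.62 and 1.61, Lgals2, a galectin, by 1.69, S100a9, a subunit of the neutrophil protein calprotectin, by 1.55, and Gas1, a growth arrest gene, by 1.54. The ranges of the groups did not overlap for any of the 93 called genes, and for 19.1% of all targets, where chance gives 10%. The number of calls depended on the variance model and on single regions. Without a mean-variance trend limma called 0 genes, with 1577 at an unadjusted p under 0.05 against 1686 with it and a smallest adjusted p of 0.0629. It called 15, 21 and 34 genes without control-labelled region 1, 2 or 3, of them 0, 1 and 1 lower, and 1024, 80 and 23 without floxed-labelled region 1, 2 or 3, of them 487, 11 and 4 lower. Of the lower genes named here, Cyp1b1 lost its call only without control-labelled region 1, Grb10 and Lgals2 kept theirs in 1 of 6 of these fits, and Ibsp, Gsta4, Tst, S100a9 and Gas1 in 2 of 6. With negative-probe scaling it called 23.

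**Figure D2:**
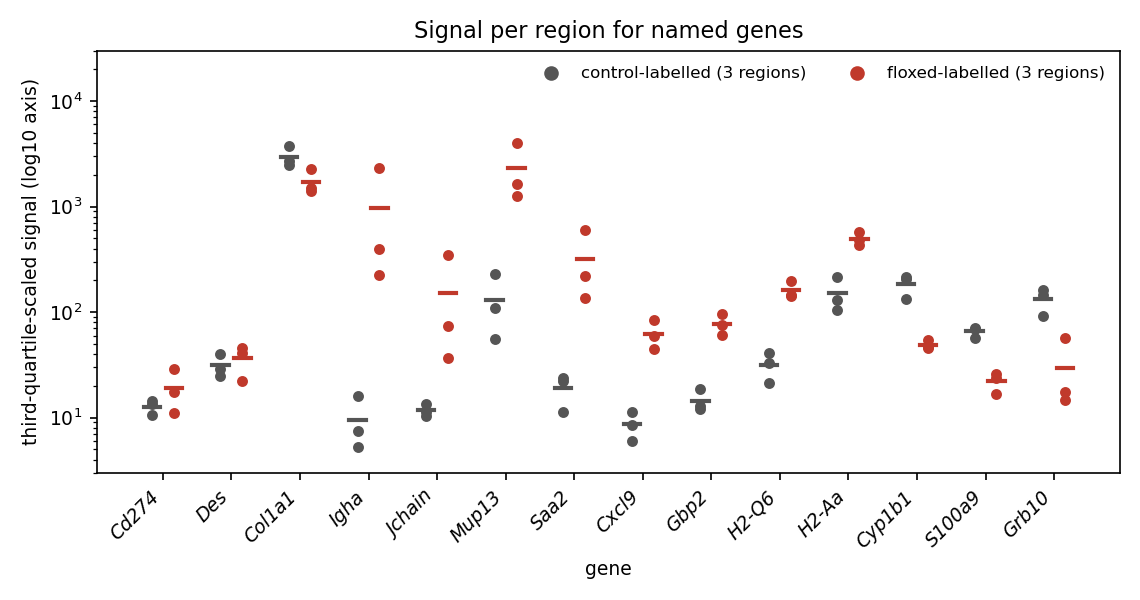
Signal of 14 named genes in every region after scaling to a common upper quartile, on a log10 axis, with a point per region and a bar at each group mean, control-labelled in grey and floxed-labelled in red. Cd274 and Des overlap between groups, Igha, Jchain, Mup13, Saa2, Cxcl9, Gbp2, H2-Q6 and H2-Aa lie higher in all 3 floxed-labelled regions, and Col1a1 (no call), Cyp1b1, S100a9 and Grb10 lie lower; on the deposited scale H2-Aa has no call (log2 change 0.46) and Cd274 and Des lie lower in the mean.

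Interferon-stimulated genes were higher in the floxed-labelled regions. Of 36 tested members 20 rose and 0 fell over all targets, and 32 rose when adjusted over the list alone. The list median was 1.72 on the log2 scale, and 30 members were higher in every floxed-labelled region than in any control-labelled region. Gbp2, a guanylate-binding protein of cell-autonomous immunity, rose from 14.4 ± 3.55 to 77.5 ± 17.2, Oasl2, an antiviral oligoadenylate synthetase-like protein, from 21.98 ± 2.71 to 104 ± 23.5, Zbp1, a sensor of unusual nucleic acids, from 10.5 ± 1.36 to 48.8 ± 10.4, and Cxcl9 from 8.63 ± 2.63 to 62.4 ± 20.1 (SD, n = 3 each). Their log2 changes were 2.35 ± 0.26, 2.18 ± 0.24, 2.10 ± 0.26 and 2.71 ± 0.30 (SE). In the control-labelled regions Zbp1 and Cxcl9 lay 2.15 and 1.78 times above the negative probe, near background, so the sizes of their changes are uncertain. The transcription factors Stat2, Irf1 and Irf7, which relay interferon signals, also passed the threshold. As deposited the list median was 0.45 against -1.22 for all targets, 9 members rose and 2 fell. Camera gave an adjusted p of 4.53e-57 as deposited and 4.89e-40 after Q3 scaling, and an adjusted p of 0.349 and 0.0542 with an estimated correlation. Fry, which asks whether the members move one way, gave an adjusted p of 0.00915 after Q3 scaling. As deposited, where the shared shift enters it and works against a rise, fry gave 0.392.

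Antigen presentation genes were also higher relative to other genes. Of 19 tested MHC class I pathway genes 8 rose and 0 fell over all targets after Q3 scaling, and 16 rose adjusted over the list alone, with a median of 1.25. H2-Q6, a class I heavy chain, read 31.6 ± 9.87 and 161 ± 30.02 (SD, n = 3 each), Tap1, a peptide transporter, 34.0 ± 8.59 and 124 ± 39.7, and the immunoproteasome subunits Psmb9 and Psmb10 read 40.1 ± 7.96 and 119 ± 18, and 51.2 ± 2.82 and 135 ± 2.12. Of 13 tested genes of MHC class II and antigen-presenting fibroblasts 6 rose and 0 fell, and 10 rose adjusted over the list alone, with a median of 1.47. H2-Aa, H2-Ab1 and H2-Eb1, which encode class II chains, changed by 1.77 ± 0.29, 1.90 ± 0.32 and 1.76 ± 0.29 (SE), and Ciita, the class II transactivator, by 1.53 ± 0.25. As deposited 1 class I gene rose and 3 fell, 0 class II genes rose and 1 fell (limma), and the medians were -0.07 and 0.26, above the -1.22 of all targets. Camera gave class I an adjusted p of 9.76e-15 as deposited and 2.86e-17 after Q3 scaling, and an adjusted p of 0.456 and 0.170 with an estimated correlation. For class II the adjusted p was 1.20e-14 and 5.71e-12, and 0.349 and 0.150 with an estimated correlation. Fry gave both lists an adjusted p of 0.0153 after Q3 scaling. As deposited, where the shared shift enters it, fry gave 0.670 and 0.970, and its direction turned to lower for both. The interferon, class I and class II lists together held 68 tested genes and 34 of the 78 higher genes, a count made after their members were seen to rise. H2 and Gbp genes are near-identical families, and a probe may bind more than its named member. Members that rose over all targets ran from 5 to 30, from 1 to 12 and from 0 to 9 in the respective lists when each region was left out in turn, with the lowest without floxed-labelled region 3 for the interferon list (5), while counts adjusted over the list alone ran from 29 to 33, from 11 to 17 and from 10 to 11. Without a mean-variance trend no member rose over all targets, and 33, 16 and 10 rose adjusted over the list alone. With negative-probe scaling 6, 1 and 0 rose over all targets, and 30, 10 and 10 adjusted over the list alone.

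Several lists of immune cell markers were also called higher by camera, though few single markers passed and the neutrophil list had no call. These calls were lost with an estimated correlation, at adjusted p of 0.339 to 0.539 after Q3 scaling. Among 23 chemokines 4 rose over all targets and 7 adjusted over the list alone: besides Cxcl9, these included Ccl19, which guides lymphocytes and dendritic cells, from 17.5 ± 5.10 to 69.1 ± 21.6 (SD, n = 3 each), Ccl5 from 10.0 ± 4.43 to 35.9 ± 6.21, and Ccl8 from 8.32 ± 1.19 to 30.7 ± 6.51. Ccl5 and Ccl8 lay 2.06 and 1.70 times above the negative probe in the control-labelled regions, near background, so the sizes of their changes are uncertain. Of 13 T and NK cell genes 0 passed over all targets and 1 adjusted over the list alone, with a median of 0.85. Trac, the T cell receptor alpha constant gene, read 8.37 ± 1.49 and 25.6 ± 10.6, and Cd8a 7.07 ± 0.97 and 15.1 ± 3.38, all near background. Cd2 read 7.21 ± 0.47 and 18.2 ± 7.79, and Cd3g 10.8 ± 2.96 and 22 ± 7.84. Of 9 B and plasma cell genes Igkc and Jchain rose. Prdm1, Ighm and Xbp1 read 14.4 ± 2.66 and 24.7 ± 5.83, 12.1 ± 1.97 and 24.7 ± 15.1, and 120 ± 14.5 and 110 ± 7.89, with no call. Of 14 dendritic cell genes 1 rose, Bst2, which is also interferon-induced, from 27.9 ± 8.95 to 107 ± 11.8, while Irf8 read 20.6 ± 4.32 and 39.2 ± 8.79, Wdfy4 17.8 ± 4.56 and 33.5 ± 9.58, and Itgae 10.2 ± 4.95 and 20.5 ± 7.07. Of 28 macrophage and monocyte genes 1 rose, Lyz2, the macrophage lysozyme, from 12.7 ± 3.83 to 48.7 ± 13.3, and 3 adjusted over the list alone. The cathepsin gene Ctss read 134 ± 54.9 and 330 ± 34.3 with an adjusted p of 0.067 (limma, Benjamini-Hochberg), Apoe 978 ± 322 and 1318 ± 496, Aif1 24.0 ± 6.92 and 51.8 ± 8.61, and Fcer1g 33.2 ± 6.49 and 60.5 ± 20.6. Among 13 neutrophil genes S100a8 and S100a9 fell, S100a8 from 31.5 ± 3.43 to 11.4 ± 1.51, and the list had no call (camera adjusted p 0.684 as deposited and 0.928 after Q3 scaling). Of these 13 changes 9 were above 0, with a median of 0.16, and adjusted over the list alone 1 gene rose and 2 fell.

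Camera placed the chemokine, T and NK, B and plasma, dendritic and macrophage lists higher than other genes on both scales. Adjusted p as deposited were 3.82e-12, 1.79e-07, 8.04e-08, 8.41e-05 and 0.0064, and after Q3 scaling 2.32e-06, 0.000242, 0.0142, 0.000586 and 0.00226. With an estimated correlation the Q3-scaled adjusted p were 0.339, 0.407, 0.339, 0.339 and 0.539. Fry called none of these lists, with adjusted p of 0.166, 0.166, 0.166, 0.166 and 0.357 after Q3 scaling. As deposited, where the shared shift enters it, fry gave 0.363, 0.327, 0.327, 0.186 and 0.143. As deposited 2 chemokines rose and 10 fell, 0 T and NK genes rose or fell, 2 B and plasma cell genes rose and 4 fell, 0 dendritic cell genes rose and 3 fell, and 0 macrophage genes rose and 11 fell (limma). All 5 list medians lay below 0 as deposited, from -0.94 for B and plasma cells to -0.35 for T and NK cells, and above the -1.22 of all targets. The macrophage call was lost in 2 of 6 fits as deposited and in 1 of 6 after Q3 scaling when each region was left out in turn, and the B and plasma call in 1 of 6 after Q3 scaling. NF-kB target genes were called higher (21 tested, median 0.22, camera adjusted p 0.0298 as deposited and 0.0213 after Q3 scaling, 0.728 with an estimated correlation), with 0 single genes passing after Q3 scaling and 13 lower as deposited. Traf1 read 8.14 ± 1.34 and 20.3 ± 8.56 (SD, n = 3 each), Tnf 7.17 ± 1.65 and 17.3 ± 5.55, Nfkbie 6.66 ± 1.96 and 14.4 ± 2.95, and Icam1 42.0 ± 4.47 and 67.8 ± 15.6. Traf1, Tnf and Nfkbie lay 1.67, 1.46 and 1.36 times above the negative probe in the control-labelled regions, near background, so the sizes of their changes are uncertain. As deposited the negative probe changed by -1.11 and the upper quartile by -1.32, so Q3 scaling raises background in the floxed-labelled regions. The list median of 0.22 is not told apart from this. The NF-kB call held in 2 of 6 fits as deposited and 3 of 6 after Q3 scaling with a region left out.

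**Figure D3:**
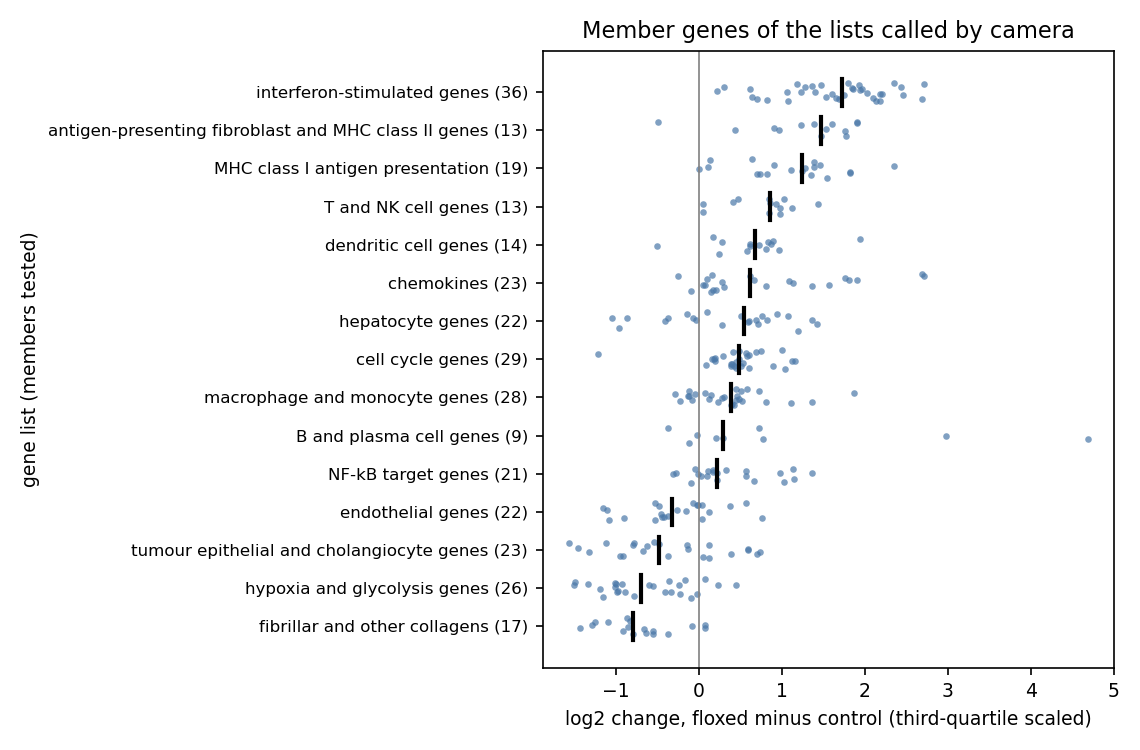
Log2 change of each tested member of the 15 gene lists called by camera on the deposited scale, here after scaling to a common upper quartile, with a point per gene and a black bar at the list median; points are spread vertically for visibility only. Medians run from 1.72 for interferon-stimulated genes to -0.80 for collagens; on the deposited scale all but the interferon and MHC class II medians lie below 0, where the median of all targets is -1.22.

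Collagen genes were lower relative to other genes. Of 17 tested collagens 0 passed over all targets after Q3 scaling and 4 fell adjusted over the list alone, with a median of -0.80. Col5a1, a regulator of fibril diameter, read 352 ± 100.4 and 145 ± 47.2 (SD, n = 3 each), Col6a1 322 ± 223 and 108 ± 40.5, Col8a1 70.4 ± 24.6 and 29.5 ± 13.5, and Col12a1 91.4 ± 5.66 and 57.7 ± 8.31. As deposited all 17 fell, with a median of -2.11 against -1.22 for all targets. Camera gave an adjusted p of 0.000133 as deposited and 2.21e-07 after Q3 scaling, and an adjusted p of 0.933 and 0.339 with an estimated correlation. Fry gave an adjusted p of 0.166 after Q3 scaling and 0.0432 as deposited, where the shared shift enters it. Matrix glycoproteins, proteoglycans and crosslinking enzymes (25 tested) were called after Q3 scaling only, with a median of -0.28 and adjusted p of 0.0142, against 0.123 as deposited and 0.539 with an estimated correlation. That call held in 3 of 6 fits with a region left out and in 5 of 8 other settings. Over all targets 1 member passed and it rose, Eln, which encodes elastin, from 42.1 ± 18.8 to 186 ± 86.3. Adjusted over the list alone 2 rose and 2 fell, and 8 of the 25 changes were above 0, while as deposited 0 members of the list rose and 20 fell. TGF-beta target genes (24 tested) were called lower after Q3 scaling only, with a median of -0.32 and adjusted p of 0.0304, against 0.0783 as deposited and 0.539 with an estimated correlation, and the call held in 3 of 6 fits with a region left out and in 3 of 8 other settings. As deposited 0 of them rose and 20 fell. Ltbp2, a latent TGF-beta binding protein family member, was the 1 member that passed over all targets and it rose after Q3 scaling, from 29.2 ± 9.89 to 94.1 ± 11.9. Fn1, fibronectin, read 804 ± 38.4 and 297 ± 128, Id1 84.7 ± 24.6 and 46.2 ± 11.9, and Tgfbi 20.7 ± 6.79 and 40.6 ± 3.36, and adjusted over the list alone 2 members rose and 2 fell.

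Contractile and inflammatory fibroblast programmes had no list call. Of 19 myofibroblast contractile genes 0 passed over all targets or adjusted over the list alone after Q3 scaling (median -0.24, camera adjusted p 0.258 as deposited and 0.122 after Q3 scaling). Acta2, smooth muscle actin, read 285 ± 105 and 163 ± 65.4 (SD, n = 3 each), Tnc 46.2 ± 23.9 and 19.99 ± 8.52, Igfbp3 862 ± 379 and 388 ± 360, and Thy1 49.4 ± 13.0 and 121 ± 99.5. Of 20 inflammatory fibroblast genes 2 rose, Ly6c1 from 29.3 ± 8.44 to 126 ± 39.9 and Dpt, dermatopontin, from 29.5 ± 4.35 to 113 ± 22.7, while as deposited 0 rose and 13 fell, and the median after Q3 scaling was 0.15 (camera adjusted p 0.301 as deposited and 0.628 after Q3 scaling). Lcn2 read 297 ± 126 and 93.8 ± 54.4, and complement C3 1920 ± 316 and 927 ± 435, both with no call over all targets, and adjusted over the list alone 2 members rose and 1 fell. Hepatic stellate cell genes (23 tested, median 0.13), pericyte and smooth muscle genes (14 tested, median -0.32), and metalloproteinases with their inhibitors (19 tested, median -0.13) had camera adjusted p of 0.438, 0.0851 and 0.294 as deposited and of 0.595, 0.0937 and 0.190 after Q3 scaling. Portal fibroblast and mesothelial genes (17 tested, adjusted p 0.685 and 0.985) had a median of -0.15 and a mean of 0.07, and Eln and Dpt rose among them, while as deposited 0 rose and 12 fell. TGF-beta ligands, receptors and SMADs (20 tested, adjusted p 0.970 and 0.900) had a median of -0.12 and a mean of 0.07, and the camera direction differed between the scales.

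Hypoxia and glycolysis genes were lower relative to other genes. Of 26 tested members 0 passed over all targets after Q3 scaling and 11 fell adjusted over the list alone, with a median of -0.70. Egln3, an oxygen-sensing prolyl hydroxylase, read 68.1 ± 21.4 and 26.0 ± 6.47 (SD, n = 3 each), Ndrg1 177 ± 61.2 and 64.6 ± 32.3, Vegfa 173 ± 78.6 and 62.5 ± 30.2, and the glycolytic aldolase Aldoa 450 ± 116 and 223 ± 64.5. As deposited 24 of 26 fell, and none rose. Camera gave an adjusted p of 9.98e-07 as deposited and 7.64e-08 after Q3 scaling, and an adjusted p of 0.933 and 0.539 with an estimated correlation. Fry gave an adjusted p of 0.431 after Q3 scaling and 0.0432 as deposited, where the shared shift enters it. Cell cycle genes went the other way relative to all targets (29 tested, median 0.48 after Q3 scaling and -0.79 as deposited, camera adjusted p 0.000684 as deposited and 1.57e-05 after Q3 scaling, 0.595 with an estimated correlation). None of them passed over all targets with limma after Q3 scaling and 1 did adjusted over the list alone, while 8 were lower as deposited. Mcm3, a subunit of the replicative helicase, read 29.99 ± 0.47 and 64.5 ± 17.8, Mcm5 19.0 ± 9.04 and 42.6 ± 17.5, Birc5 11.5 ± 0.77 and 25.5 ± 11.1, and Ccna2 19.0 ± 4.22 and 32.4 ± 6.01. Genes of the mitochondrial respiratory chain (28 tested, median -0.23) were called lower after Q3 scaling only, at an adjusted p of 0.00247, against 0.122 as deposited and 0.595 with an estimated correlation, and the call held in 5 of 6 fits with a region left out and in 5 of 8 other settings.

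Markers of neighbouring tissue moved in different directions. In the control-labelled regions Col1a1, Spp1, Alb and Krt8 lay 610, 575, 481 and 175 times above the negative probe, and Des 6.43 times. The mask therefore does not rule out RNA of tumour and liver cells. Whether a different mix of tumour, liver and vessel cells carries other gene or list changes was not tested. Tumour epithelial and cholangiocyte genes were lower relative to other genes (23 tested, median -0.49 after Q3 scaling and -1.78 as deposited, camera adjusted p 0.0254 as deposited and 0.00226 after Q3 scaling, 0.339 with an estimated correlation). Spp1, osteopontin, read 2830 ± 953 and 1189 ± 1017 (SD, n = 3 each), Krt8 857 ± 166 and 545 ± 176, Sox4 151 ± 10.8 and 61.4 ± 32.7, and Sox9 58.7 ± 12.0 and 30.2 ± 19.8, with no single call over all targets and 1 gene lower adjusted over the list alone. Cd24a read 295 ± 57.3 and 149 ± 133. Hepatocyte genes were higher relative to other genes (22 tested, median 0.55 after Q3 scaling and -0.75 as deposited, camera adjusted p 0.00856 as deposited and 0.0374 after Q3 scaling, 0.779 with an estimated correlation). Albumin, Alb, read 2364 ± 532 and 3344 ± 1990, Apoa1 691 ± 178 and 1253 ± 637, Apoa2 368 ± 149 and 772 ± 278, Fgg 248 ± 93.9 and 564 ± 208, Ass1 47.1 ± 9.30 and 75.9 ± 7.27, and Tdo2 10.6 ± 1.06 and 30.2 ± 12.7, with no single call over all targets and 1 gene higher adjusted over the list alone, and as deposited 0 genes of the list rose and 9 fell. Endothelial genes were lower relative to other genes (22 tested, median -0.32 after Q3 scaling and -1.53 as deposited, camera adjusted p 0.00826 as deposited and 0.0336 after Q3 scaling, 0.779 with an estimated correlation). Flt1 read 110 ± 13.0 and 50.9 ± 9.08 with an adjusted p of 0.0505 (limma, Benjamini-Hochberg), Esam 51.0 ± 20.4 and 24.7 ± 14.4, Podxl 67.2 ± 6.56 and 39.0 ± 33.4, Cdh5 92.3 ± 52.2 and 43.2 ± 15.5, and Eng 74.6 ± 36.6 and 103 ± 69.1, and adjusted over the list alone 1 gene of the list fell. With a region left out, the endothelial call held in 2 of 6 fits on both scales, the hepatocyte call in 4 of 6 as deposited and 2 of 6 after Q3 scaling, and the tumour epithelial call in 3 of 6 as deposited. For the tumour epithelial, hepatocyte and endothelial lists fry gave adjusted p of 0.198, 0.697 and 0.772 after Q3 scaling. As deposited, where the shared shift enters it, fry gave 0.0432, 0.273 and 0.0889.

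The other tested lists had no call on either scale. These were immune checkpoint ligands and receptors (19 tested, median 0.34, camera adjusted p 0.771 after Q3 scaling), growth factors and angiogenic factors (29 tested, median 0.03, mean -0.04, 0.595), cytosolic ribosomal proteins (36 tested, median -0.08, 0.0963, higher than other genes as deposited and lower after Q3 scaling), the unfolded protein response and heat shock (18 tested, median -0.04, 0.553), immediate early genes (17 tested, median 0.07, test direction lower, 0.944), p53 targets and senescence (15 tested, median -0.07, 0.421), apoptosis and necroptosis (19 tested, median -0.11, 0.668), and lipid and retinoid metabolism (21 tested, median -0.11, 0.506). In the last list Scd1, a lipid desaturase, rose from 39.9 ± 8.67 to 170 ± 75.2 (SD, n = 3 each), while as deposited 0 members rose and 17 fell. Muscle genes (4 tested) and erythroid and platelet genes (3 tested) were too few for the list test. Hba-a1, a globin, read 144 ± 90.0 and 108 ± 128, Pf4 12.6 ± 2.49 and 13.2 ± 4.65, and the muscle gene Tnnt3 9.25 ± 3.18 and 9.42 ± 5.12. Among further abundant markers, Mcam and Rgs5 of pericytes read 101 ± 40.3 and 44.4 ± 15.5, and 88.4 ± 29.0 and 51.8 ± 30.6, Gas6 and Krt19 of the portal and mesothelial list 497 ± 88.8 and 289 ± 314, and 397 ± 87.5 and 240 ± 95.8, Fscn1 of dendritic cells 46.2 ± 12.6 and 31.4 ± 2.69, and Cd247 of T and NK cells 13.1 ± 2.10 and 19.6 ± 8.47. Of the 34 tested lists, 15 were called as deposited and 18 after Q3 scaling, 15 of them on both scales, and 0 with an estimated correlation on either scale, where the smallest adjusted p was 0.349 and 0.0542. Fry called 3 after Q3 scaling, those of interferon, MHC class I and MHC class II genes. In other splits of the 6 regions camera called 6 to 12 lists as deposited and 6 to 13 after Q3 scaling. Those splits keep part of a difference between the labelled groups, so these counts are no rate of false calls. Since 0 lists were called with an estimated correlation, a camera call alone is weak evidence for a single list.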

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

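The scalings by Q3, total, quantile and negative probe for the as-deposited result, and the filters, pseudocounts, variance models, weights, threshold and left-out regions, were chosen before the data were examined, except for negative-probe scaling beyond the 4 marker genes, negative-probe subtraction and the whole Q3-scaled comparison. The count-based tests foreseen for raw or recovered counts were not run, because whole tag numbers were not established for all columns. No paired analysis was possible because no label ties a floxed-labelled region to a control-labelled one. The filter on low values removed no target, so its omission tested nothing. If a step is 1 tag, the median target rested on 11 to 19 tags in the floxed-labelled regions, which limits low genes there. As deposited, 21 genes were higher and 9905 lower. Scaling gave 78 and 15 (Q3), 82 and 16 (total), 67 and 13 (quantile) and 18 and 5 (negative probe), since it removes the shared shift, and 32, 33, 28 and 18 of the 9926 calls were still called. Only genes above the median mean left 5895 lower (fewer genes tested), region weights gave 57 higher and negative-probe subtraction 35 higher. With each region left out, higher calls ran from 9 to 41 and lower calls from 5716 to 9738. Cd274 turned from -0.76 to 0.47 (Q3), 0.49 (total), 0.33 (quantile) and 0.28 (negative probe). It passed at -0.76 with the threshold of 0.1, and ran from -1.19 to -0.53 with a region left out, passing without floxed-labelled region 3 (adjusted p 0.0162, limma; 0.0162 to 0.252 over the left-out regions). Des turned to 0.18, 0.20 and 0.19 (Q3, total, quantile), and Ptprc to 0.80, 0.82, 0.83 and 0.60 (Q3, total, quantile, negative probe). Of 34 lists, 15 were called by camera, 11 higher and 4 lower, 0 with an estimated correlation and 12 to 18 under its other settings. Fry called 18, with the direction lower for 33 of the 34 lists, so a like count is not the same lists. Of 399 values for 20 genes under these settings, 350 kept direction and side of the threshold, 36 lost the call, 2 gained it and 11 reversed.

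After Q3 scaling, 78 genes were higher and 15 lower. Without a variance trend limma called 0 and 0 (1577 at an unadjusted p under 0.05), with region weights 365 and 330, with negative-probe scaling 18 and 5, as deposited 21 and 9905, and with the threshold of 0.1 115 and 52. With a region left out, higher calls ran from 15 to 537 and lower calls from 0 to 487, and the cause was not tested. Of 18 called lists, 11 were called above the median mean, 3 by fry, 0 with an estimated correlation, and 12 to 20 under the other settings. Of 1744 values for 88 genes, 1441 kept direction and side of the threshold, 169 lost the call, 106 gained it and 28 reversed. As deposited, where the median target shifts by -1.22, the log2 changes that reversed were Cd274 -0.76, Des -1.10, Ptprc -0.48, Tgfbi -0.29, Thy1 -0.29, Traf1 -0.074, Tnf -0.069, Icam1 -0.63, Nfkbie -0.16, Fgg -0.12, Ass1 -0.60, Apoa2 -0.24, Aif1 -0.17, Fcer1g -0.48, Cd2 -0.079, Cd3g -0.30, Cd8a -0.22, Prdm1 -0.52, Ighm -0.47, Irf8 -0.38, Wdfy4 -0.40, Itgae -0.25, Mcm3 -0.25, Birc5 -0.25, Mcm5 -0.11 and Ccna2 -0.52. Des also turned to -0.0236 with negative-probe scaling and ran from -0.0179 (without floxed-labelled region 3) to 0.49 with a region left out.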

Other observations

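Of the 93 genes called after Q3 scaling, 46 belong to no fixed gene list, and the genes and groupings named here were chosen after their values were seen, with no test of enrichment. Some are known to respond to interferon. Gvin1, a large interferon-induced GTPase, rose from 15.5 ± 5.20 to 91.6 ± 12.1 (SD, n = 3 each), Samhd1, a dNTP hydrolase that restricts viruses, from 32.3 ± 3.19 to 91.3 ± 15.6, and Slfn5, Sp110, Dhx58, Rtp4, Oas1b and Parp9 changed by 1.71, 1.59, 1.54, 1.34, 1.33 and 1.30 on the log2 scale. Others are known from hepatocytes, although of the 22 tested genes of the fixed hepatocyte list 0 rose over all targets, 8 changes were below 0 and the adjusted p was 0.779 with an estimated correlation (camera). Car3, a carbonic anhydrase, rose from 7.46 ± 2.27 to 58.4 ± 45.7, Mbl2, a secreted lectin of complement, from 14.5 ± 1.89 to 57.4 ± 10.7, the bile acid synthesis enzymes Cyp8b1 and Cyp7b1 by 1.67 and 1.58, and Sult2a8, Aox3, Cyp1a2, Apof and Slc27a2 by 2.34, 1.95, 1.52, 1.39 and 1.28. Albumin, the most abundant hepatocyte marker, changed by 0.28 with no call (limma, adjusted p 0.868, Benjamini-Hochberg).

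Pdpn, podoplanin, a glycoprotein of fibroblasts and lymphatic vessels, rose from 35.4 ± 4.96 to 92.9 ± 20.3 (SD, n = 3 each), and C1s1, a protease of the complement pathway, from 25.9 ± 10.6 to 74.9 ± 3.19. The leukocyte genes Cd52, Dock2, Ly86 and Fgl2 changed by 1.32, 1.31, 1.10 and 1.70. Among the lower genes, Ahcy, which hydrolyses S-adenosylhomocysteine, read 156 ± 8.62 and 68.3 ± 10.8, Ddit4, a stress-induced inhibitor of mTORC1, 77.7 ± 15.9 and 33.1 ± 2.998, and Errfi1, a feedback inhibitor of the EGF receptor, 129.9 ± 10.6 and 51.6 ± 10.8, while Mkrn1, Rap1gap and C1qtnf6 fell by 1.24, 1.45 and 1.49. Each of the genes named as called had floxed-labelled values that did not overlap the control-labelled ones.

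All tests in the following paragraphs were chosen after the results they address were seen. Deposited signal was lower in the floxed-labelled regions, and 9926 genes were called, against at most 0 in the other 9 of the 10 splits of the 6 regions, too few for a share under 0.05. Those other splits place both labels in each group, so the shared shift widens the spread within their groups. Their lack of calls therefore adds no support. Less target RNA over an unchanged background would leave the negative probe level, but it fell to 0.460 of the control-labelled mean, by -1.11 on the log2 scale, close to the -1.22 of the median target. A factor shared by all probes of a region, such as sequencing depth, collected area or scaling, remains a candidate explanation, and a difference in RNA content that also changes such a factor was not tested. Column totals in steps were 862301 ± 169172 (control-labelled) and 323534 ± 133422 (floxed-labelled; SD, n = 3 each), a 2.67-fold difference. If a step is 1 tag, this argues against the scaling before deposit as the source, but whole tag numbers were not established for all columns. As for lists, 15 were called in the real split and at most 12 in another.

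Interferon, MHC class I and MHC class II genes were higher relative to other genes by camera after Q3 scaling, a call lost with an estimated correlation (adjusted p 0.0542, 0.170 and 0.150). The choice of a scaling factor moves all genes alike, but the interferon list, fixed before the data were examined, lay 1.70 above the median of all genes (95% interval over genes 1.37 to 1.92), against at most 0.72 in another split of the regions, with 1.22 against 0.656 for class I and 1.45 against 0.875 for class II. A factor per region leaves such a difference nearly unchanged whatever its size, so these values speak only to such a factor. The interval over genes holds no spread between regions. Every other split mixes the labels within its groups, which dilutes a difference between the labelled groups. The split values therefore add no support of their own. More macrophage RNA in the mask would raise macrophage genes at least as much as MHC class I genes. The median of the macrophage genes instead lay -0.856 relative to the class I genes (interval over genes -1.16 to -0.34). The interval holds no spread between regions, so it does not exclude more macrophage RNA. The interferon and class II genes were not compared with the macrophage genes in this way, and dendritic cell RNA was not tested. A change of state within macrophages stays possible. The mask was chosen to leave out CD45-positive cells, but RNA of Ptprc, which encodes CD45, was read in it. Ptprc lay on average 5.35 (control-labelled) and 8.28 (floxed-labelled) times above the negative probe, with no call. The mask therefore does not rule out leukocyte RNA. More T and NK cell RNA stays open, since these genes were higher too (median 0.85, and 1.38 with the negative probe subtracted against 1.29 for MHC class I), but at a median of 2.69 times the negative probe, with 0 of 13 over 5 times, they lie too near background to decide it. The genotype, the animal and the position in the tumour were not told apart by any test, and 93 genes were called after Q3 scaling in the real split against at most 1 in another (18 lists against at most 13), with 10 splits too few for a share under 0.05.

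Igha, Igkc and Jchain were higher in each floxed-labelled region. A background signal that follows the mask would stay near the negative probe, but Igha lay at least 41.8 times above it in the floxed-labelled regions. While Igha varied 10.2-fold between these regions, its ratio to Jchain was 6.64, 5.38 and 6.09, a spread of 1.23-fold (6.72, 5.84 and 6.96, or 1.19-fold, with the negative probe subtracted, where Igha varied 10.4-fold), so RNA of a single source, such as plasma cells near the mask, is a candidate explanation. The plasma cell genes Xbp1, Sdc1 and Prdm1 changed by -0.13, -0.03 and 0.72 with no call (limma, adjusted p 0.851, 0.983 and 0.320), and fibroblasts also express Xbp1 and Sdc1. Whether the genotype, the animal or the place in the tumour set the amount was not tested.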
